A study of Mus musculus with 6 samples.

How the data were processed

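Gene expression was measured on 6 Illumina bead arrays, each hybridised with RNA from mouse Sertoli cells sorted by fluorescence. The labels place 3 arrays in an Rb1 conditional knockout group (cKO) and 3 in a control group. Nothing in the labels says whether the arrays of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. Per the labels' protocols, RNA was extracted with a column kit for small samples, its quality was inspected by capillary electrophoresis, and biotinylated cRNA was made with an amplification kit for Illumina arrays. BeadStudio is named in the submitters' processing notes, without a version.

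Per the file headers, each array's table holds the mean intensity of each probe, the spread between its beads, the number of beads and a detection score. These intensity values are linear, hold none below 0 and were not scaled between arrays as far as the values show. The deposited detection score rises with signal from 0 to 1, and a score over 0.95 was taken as detection, which stands for a detection p-value under 0.05. The deposited series table holds log2 values. Set against the scanner tables, these log2 values equal the log2 intensity minus the array's 75th percentile, centred on each probe's median over the 6 arrays; the tool for that step is not given in the sources used here. The medians of its columns were 0.244, -0.022 and -0.194 for cKO replicates 1 to 3, and 0.040, 0.098 and -0.301 for the controls.

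The scanner tables name probes by number and the gene annotation by probe ID. The identifiers were joined through this formula: all 45281 table entries had 1 scanner probe of their own within 0.00069, and the match was the same from any 5 arrays for 100% of entries. The smallest distance to a second probe was 0.0042. The platform annotation gave 1 gene symbol for 34885 probes, several for 18 and none for 10378. The Entrez ID of 34807 probes was in a gene table of the GRCm38.p6 assembly, and no symbol changed. No probe with several genes was named, and no coordinates are given because no build is named for the arrays.

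Intensities were background-corrected and quantile-normalised with neqc in limma 3.58.1 (R 4.3.3), with the background estimated from the detection values and an offset of 16. Probes detected on at least 3 of the 6 arrays were tested, whatever their group, which left 21805 probes for 12277 genes. Groups were compared with limma's lmFit and eBayes, two-sided, with group as the only term and Benjamini-Hochberg adjustment at 0.05. Gene lists were tested with camera at a preset correlation of 0.01, on the brightest tested probe of each gene, for lists with at least 5 measured genes. Camera with an estimated correlation and fry were run beside it. All adjusted p-values come from limma unless another test is named. For a probe not above background on any control array, a bound is given as "at least N-fold": the mean of the cKO arrays over the control mean of, per array, the higher of the probe's own value and the lowest value of a detected probe, all as means of normalised log2 values.

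The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took every Rb1 probe, then, ranking each gene by its brightest tested probe alone, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose arrays did not overlap. Where under 5 passed in a direction, the 5 with the smallest p were taken as values that did not pass. It also took up to 4 members of each list with the smallest p. Clone and predicted names were passed over, which was 1 gene. Genes named outside this rule are marked as chosen after their values were seen.

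Both groups carry replicate numbers 1 to 3 in their titles. Deviations from the group means correlated between same-numbered arrays at 0.262, 0.410 and 0.473, all over 0.1, across the tested probes. By the rule fixed for this check, the numbers were taken as pairing the samples. They entered only as a block in an alternative, and the main fit and list tests kept group as the only term. The labels do not say what a shared number stands for, and the pairing comes from these correlations only.

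The fit and the list tests were tested on data simulated from the real probe means and residual spread for the comparison of 3 and 3 arrays, with 200 of 21805 probes changed in each of 10 runs. Of the changed probes, 0.80% were called at a 2-fold change, 41.8% at 4-fold, 70.4% at 8-fold and 83.0% at 16-fold. Of all calls, 4.67% were probes that had not been changed. Quantile normalisation understated simulated falls, by 0.18 ± 0.03 (SE) log2 units at 8-fold and 0.22 ± 0.03 at 16-fold. Without that step the mean errors were 0.03 and 0.03, and simulated rises at 8-fold were off by -0.01 with it. Large falls were therefore measured less fully than large rises in these simulations. The simulations normalised the tested probes alone, whereas the real arrays were normalised over all probes before the filter. The size of this understatement may thus differ in the real data. A list shifted by 1 log2 unit was called in all 10 runs, and an unshifted list was called 1 time over these runs. The simulated probes varied independently, unlike those of the real arrays.

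The alternatives were other background corrections and normalisations, the deposited log2 values, other filters on dim probes, the replicate block, other variance models, a fold threshold, 1 probe per gene, and leaving out each array. The arrays are too few for more than a coarse estimate of spread. Slides are not named in the tables, so a slide could not be entered as a block.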

Results

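Transcript levels were compared in Sertoli cells, the somatic cells that support germ cells in the seminiferous tubules, from mice 6 weeks old of a mixed C57B6J/129SvEv background. The cells carried a Sox9-GFP reporter, which marks Sertoli cells in the testis, and were sorted by fluorescence. In the cKO samples, Cre recombinase under the Amh promoter acts on a floxed allele of Rb1, the retinoblastoma gene, whose other allele is null. The controls had the same floxed and null alleles without Cre, so they carry a single intact copy. There were 3 arrays per group, each with 45281 probes and a median of 43 to 44 beads per probe. The share of probes detected was 43.0%, 47.4% and 50.04% on cKO replicates 1 to 3, and 46.4%, 46.0% and 53.5% on the controls. The comparison asks how loss of Rb1 alters Sertoli cell gene expression.

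The array of cKO replicate 1 and that of control replicate 3 stood apart from the rest. They lay at -113.9 and 110.2 on a first principal component that held 58.9% of the variance, and the other 4 arrays lay between -34.3 and 31.4. Pairwise correlations of the arrays ranged from 0.799 to 0.973.

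Rb1 itself was measured by 2 probes, and both gave lower values in cKO. Probe ILMN_2679619 averaged 7.80 ± 0.40 (SD, n = 3) in cKO and 9.02 ± 0.35 in controls on the log2 scale, a difference of -1.22 ± 0.32 (SE) with an adjusted p of 0.399 in limma. Probe ILMN_2861644 gave -0.98 ± 0.34, with an adjusted p of 0.668. The cKO and control arrays did not overlap for either probe, yet neither passed the threshold. Where the probes lie relative to the deleted part was not determined, and a probe outside it checks nothing about the deletion.

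In this comparison a small set of genes passed the threshold as higher in cKO. Only the cKO samples carried Cre, so an effect of Cre itself cannot be told apart from loss of Rb1. Ranked by each gene's brightest tested probe, Timp1, an inhibitor of matrix metalloproteinases, rose most, by 6.02 ± 0.37 (SE) log2 units, or 64.9-fold, from 6.45 ± 0.12 (SD, n = 3) in controls to 12.47 ± 0.67 in cKO. Its other probe rose by 6.09. Serpina3n, a serine protease inhibitor of the acute phase response, rose by 5.14 ± 0.55. The probes of Cd83, a surface protein of activated dendritic cells and lymphocytes, and of Fas, a death receptor, were not above background on any control array, and were at least 15.1-fold and 15.4-fold higher in cKO. Gbp3, an interferon-induced GTPase, rose by 3.42 ± 0.35, and Tgm2, a transglutaminase, by 3.13 ± 0.34. Cyp1b1, a cytochrome P450, rose by 3.28 ± 0.36, Emp1, a membrane protein, by 3.06 ± 0.38, and the tetraspanin Cd63 by 2.93 ± 0.36. The probes of the remaining genes named by the rule were not above background on any control array: Pqlc3 was at least 7.43-fold higher, the tight junction gene Cldn4 at least 6.69-fold and Exoc3l4 at least 6.09-fold. Adjusted p-values of these 12 genes ran from 0.00744 to 0.0499.

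**Figure D1:**
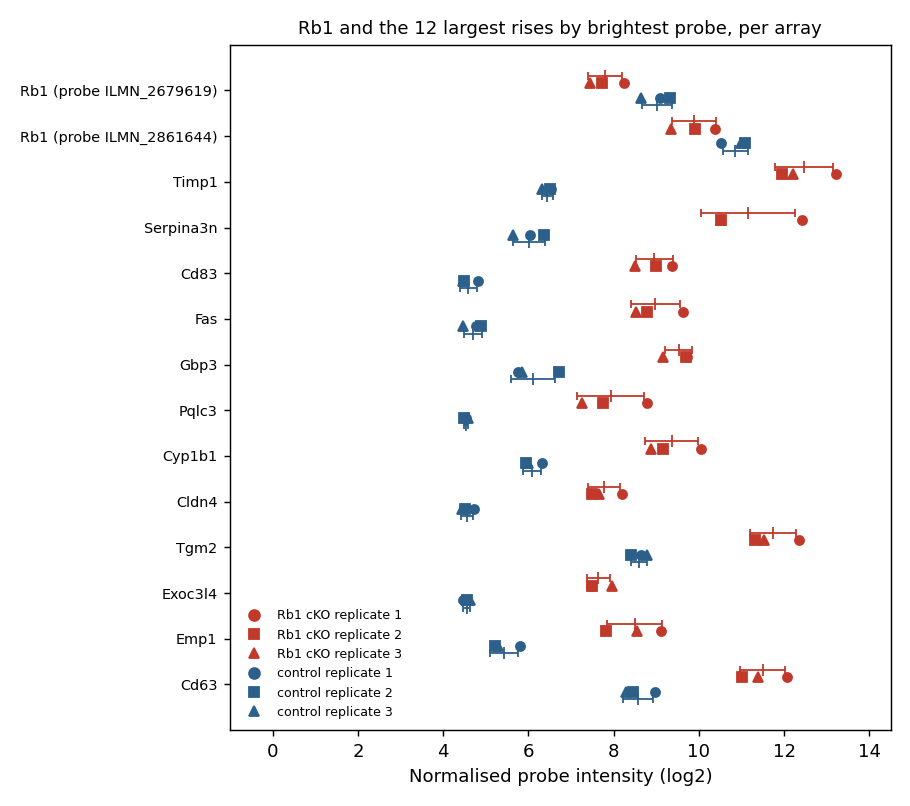
Normalised probe intensity (log2, x axis) of both Rb1 probes and, by each gene's brightest tested probe, of the 12 genes with the largest rises on each array, with symbols for the replicates and bars for the group mean ± SD (n = 3). For each of the 12 genes the cKO arrays lie above the control arrays, and for both Rb1 probes they lie below.

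In all, 31 of 21805 tested probes were higher in cKO and 0 were lower at an adjusted p under 0.05 in limma. These probes stood for 26 named genes, with 4 probes that had no single gene symbol, and all 31 separated the cKO from the control arrays. At an unadjusted p under 0.05 there were 1010 higher and 383 lower probes, and the groups did not overlap for 12.1% of probes, against 10% by chance. The 5 genes with the smallest p among those lower did not pass: Trnp1 at -2.30 ± 0.40, Sstr2 at -1.88 ± 0.33, Cldn3 at -2.07 ± 0.48, Tspan2 at -1.12 ± 0.26 and Insr at -1.23 ± 0.29, with adjusted p from 0.124 to 0.302. Of 52 other probes of the named genes, 29 (of 25 genes) had the opposite sign or under 0.5 times the size: of the other Pqlc3 probes, 1 was at least 3.06-fold higher and 1, detected on all 3 control arrays, gave 0.52, and another of Insr gave 0.12. With the replicate number as a block limma called 0 probes (1975 higher and 1282 lower at an unadjusted p under 0.05; smallest adjusted p 0.0529). It called 0 probes without control replicate 1, 2 or 3 (2620, 1057 and 873 at an unadjusted p under 0.05), 2, 8 and 16 without cKO replicates 2, 1 and 3, and 6 without both cKO replicate 1 and control replicate 3.

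Genes of DNA replication were higher in cKO as a group. Of 32 measured E2F targets of S phase, all 32 had a positive difference, with a median of 1.01, and the 3 cKO arrays exceeded the 3 controls for 25, where chance gives 10% of genes on either side together (camera adjusted p 3.87e-20; adjusted p = 0.212 with an estimated correlation). Adjusted over all probes, 1 passed, Cdt1, a factor that licenses replication origins, which rose by 2.16 ± 0.27. Adjusted over the list alone, 25 passed, all higher. The helicase subunits Mcm2 and Mcm4 differed by 2.36 ± 0.42 and 1.29 ± 0.25, and the polymerase subunit Pold1 by 1.44 ± 0.27, with adjusted p over all probes of 0.124, 0.157 and 0.157. The list median was 0.84 without the 2 arrays that stood apart. Of the spermatogonia markers, which dividing germ cells would bring, the median was 0.67.

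Mitosis genes were also higher as a list, with a median of 0.74 over 27 measured genes and 25 positive differences (camera adjusted p 2.80e-06; adjusted p = 0.283 with an estimated correlation). The centromere histone Cenpa rose by 2.68 ± 0.26 and was the only member to pass, both over all probes and adjusted over the list alone. Anln, Mad2l1 and Birc5 differed by 1.02, 0.86 and 0.85 without passing, and other Birc5 probes by 0.32 and 0.03. The list median was 0.43 with the deposited log2 values, 0.44 without the filter on dim probes and 0.43 without the 2 arrays that stood apart. Spermatogonia markers had a median of 0.67. The pocket protein and E2F family list was not called (adjusted p 0.321, median 0.28, from 0.13 to 0.56 over the alternatives). Its member E2f1, a transcription factor held by the Rb protein, differed by 3.31 ± 0.42 with an adjusted p of 0.0501, and it passed adjusted over the list alone (1 of 11). With 1 probe per gene its adjusted p was 0.0190, and over all alternatives it ran from 0.00120 to 0.348. Rbl1 differed by 1.34 (another probe 0.22) and E2f3 by 0.75 (another probe 0.26). The list of D cyclins, their kinases and CDK inhibitors was not called (adjusted p 0.708). In it Cdkn2a was at 1.22 (another probe 0.36), Ccnd1 at 0.92, Cdkn1c at 0.87 and Cdkn2d at -0.90. On cKO replicates 1 to 3 Cdkn2d was at 7.72, 9.10 and 9.85, with a control mean of 9.79. None of the 11 list members passed adjusted over the list alone.

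Inflammation and interferon response genes showed the largest list median, 1.43 over 20 measured genes, with 19 positive differences (camera adjusted p 2.17e-16; adjusted p = 0.212 with an estimated correlation). The adhesion molecules Icam1 and Vcam1 rose by 2.55 ± 0.26 and 2.29 ± 0.27, although another Vcam1 probe gave 0.58. Adjusted over the list alone, 14 passed, all higher. The chemokine Cxcl2, not above background on control arrays and at least 4.23-fold higher, and the siderophore-binding protein Lcn2 at 3.35 ± 0.59 had adjusted p over all probes of 0.0969 and 0.124. The list median was 0.94 without the filter on dim probes and 1.30 without the 2 arrays that stood apart, and the macrophage and leukocyte markers had a median of 0.69.

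Targets of p53 were higher as a list, with a median of 0.50 over 18 measured genes (camera adjusted p 5.41e-05; adjusted p = 0.304 with an estimated correlation). Besides Fas, the BH3-only gene Bbc3, the apoptosome gene Apaf1 and the cyclin Ccng1 differed by 2.45 ± 0.39, 1.49 ± 0.31 and 1.49 ± 0.34. These 4 genes passed adjusted over the list alone, and of them only Fas passed over all probes. Another Bbc3 probe gave 0.64. The list median was 0.33 without cKO replicate 1. The apoptosis machinery list was not called (adjusted p 0.257, median 0.08, from -0.00017 to 0.18 over the alternatives). Of its 20 members 2, Fas and Apaf1, passed adjusted over the list alone. Casp8 and Casp1 differed by 0.94 and 1.07. Extracellular matrix and basement membrane genes were higher, with a median of 0.48 over 24 genes (camera adjusted p 0.0121; adjusted p = 0.283 with an estimated correlation; 0.0702 with the replicate block). Besides Timp1, Mmp9, Col4a1 and Col4a5 differed by 1.55, 1.51 and 1.88, and 5 members passed adjusted over the list alone. This list was not called without cKO replicate 3 (adjusted p 0.201) or without control replicate 1 (0.0726), and its median was 0.22 without control replicate 3. The median was 0.25 with normexp at offset 50, 0.32 without background correction, 0.23 without the filter on dim probes and 0.32 without the 2 arrays that stood apart. Peritubular and endothelial markers had medians of 0.76 and 0.74. Immediate early and heat shock genes were not called (adjusted p 0.0735, median 0.20). Atf3 differed by 3.03 ± 0.41, Fos by 1.64, Ier3 by 1.42 and Egr2 by 1.05, and 3 of 16 passed adjusted over the list alone. Camera called the list as higher in 9 of 16 alternatives: the deposited log2 values (0.0137), detection on all 6 arrays (0.0194), normexp at offset 50 (0.0405), no filter on dim probes (0.0424), no background correction (0.0466), median scaling (0.0474), and without cKO replicate 1 (0.00830, median 0.44), control replicate 3 (0.00279, median 0.11) or both (0.000127). The median was also 0.44 without control replicate 2.

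Markers of mature Sertoli cells were lower as a list, with a median of -0.43 over 27 measured genes and 25 negative differences (camera adjusted p 2.28e-06; adjusted p = 0.283 with an estimated correlation). No member passed, over all probes or adjusted over the list alone. Markers of other cells had medians of 0.76 (peritubular), 0.74 (endothelial), 0.69 (leukocyte) and 0.67 (spermatogonia). Sox8 differed by -1.04 ± 0.44, the iron carrier Trf by -2.54 ± 1.25, Dhh by -0.52 ± 0.27 and Gdnf by -0.64 ± 0.34. On cKO replicates 1 to 3 Trf was at 4.57, 7.77 and 9.97, so much of its difference came from replicate 1. The per-array list means, relative to the control mean, were -1.26, -0.39 and -0.18 for cKO replicates 1 to 3 and -0.25, 0.03 and 0.21 for the controls. The median was -0.29 with the deposited log2 values and -0.21 without cKO replicate 1. Without the 2 arrays that stood apart it was -0.18 and the list was not called (adjusted p 0.0921). Androgen-responsive genes were lower, with a median of -0.34 over 12 genes (camera adjusted p 0.0110; adjusted p = 0.314 with an estimated correlation). Adjusted over the list alone, Cldn3 and Corin passed as lower, at -2.07 and -1.18, and Serping1 as higher, at 1.84; Drd4 was at -0.96. The median was -0.18 with the deposited log2 values. That list too was not called without these 2 arrays (adjusted p 0.151, median -0.12), nor without cKO replicate 1 (0.0563, median -0.078).

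Other Sertoli cell lists were not called. For immature Sertoli markers the adjusted p was 0.429 and the median 0.34, from 0.14 to 0.43 over the alternatives. Gjb2 was at 1.23, Igf2 at 1.06, Ncam1 at 1.20 (another probe -0.0055) and Sox4 at -0.54 (another probe -0.020). The blood-testis barrier list had an adjusted p of 0.208 and a median of -0.07 with a mean of 0.01, so the 2 differed in sign. Over the alternatives its median ran from -0.20 to -0.045. Camera called the list as lower without the filter on dim probes (0.0349). In it Ocln was at -1.01 and Jam2 at 1.03, with other Jam2 probes at 0.62, 0.0065, -0.086 and -0.59. Secreted factors had an adjusted p of 0.814, with Pdgfb at 2.04, Cxcl12 at 1.15 and Pdgfa at 0.49, and 1 of 15, Pdgfb, passed adjusted over the list alone. Retinoid handling had an adjusted p of 0.493 and a median of -0.16 with a mean of 0.04, with Rbp4 at least 1.52-fold higher, Cyp26a1 at -0.77, Rarg at 0.69 and Rxra at 0.90. Cholesterol synthesis had an adjusted p of 0.210, with Stard4 at 1.34, Insig1 at 1.23, Mvk at 1.16 and Srebf2 at 0.86. For glucose use and lactate the adjusted p was 0.0993. Pdk1 was at -1.44, Pgam1 at -1.32 (another probe -0.11), Pfkl at -0.44 (another probe 0.049) and Tpi1 at 0.41. Much of 2 of these came from cKO replicate 1: on cKO replicates 1 to 3 Pdk1 was at 7.90, 9.64 and 9.99, and Pgam1 at 6.67, 8.53 and 9.16.

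Markers of other testis cells were measured as well. Spermatogonia markers were higher in cKO, with a median of 0.67 over 12 genes (camera adjusted p 0.00316; adjusted p = 0.292 with an estimated correlation), with Dppa4 at 1.23, Ret at least 1.57-fold higher, Dazl at 0.90 and Sohlh1 at 0.68. None passed adjusted over the list alone, the call was lost with the deposited log2 values (0.0504), and the median was 0.31 without the 2 arrays that stood apart. Spermatocyte and spermatid lists were not called (adjusted p 0.268 and 0.250, medians 0.34 and 0.36). Camera called spermatids as higher without cKO replicate 1 (0.0407), without control replicate 1 (0.0191, median 0.56) and without the 2 arrays that stood apart (0.0263, median 0.23), and spermatocytes without control replicate 3 (0.0310, median 0.21). Their members with the smallest p were Meiob, Ccna1, Tex101 and Ybx2 at 0.79, 0.66, 0.66 and 0.51, and Gapdhs, Cabyr, Akap4 and Tssk6 at 0.82, 0.44, 0.44 and 0.43. Other probes gave -1.99 and 0.47 for Akap4, -0.28 for Cabyr, -0.042 for Ybx2 and 0.63 for Gapdhs. Prm1, a protamine of spermatids chosen after its values were seen, was at 14.82 in cKO and 14.84 in controls, so germ cell RNA was abundant in both groups. Peritubular myoid markers were higher (median 0.76, 8 genes, camera adjusted p 0.0289; adjusted p = 0.283 with an estimated correlation; 0.0798 with the replicate block), with Acta2 at 1.81, Tpm2 at 1.33, Tpm1 at 0.91 and Des at 0.77. This call was also lost with the deposited log2 values (0.156), with detection on all 6 arrays (0.0505), without control replicate 1 (0.103) and without cKO replicate 3 (0.358). The median was 0.44 with the deposited log2 values, 0.42 without the filter on dim probes and 0.49 without the 2 arrays that stood apart.

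Macrophage and leukocyte markers were higher (median 0.69, 10 of 20 genes measured, camera adjusted p 0.0149; adjusted p = 0.339 with an estimated correlation), with Cd74 at 1.70, H2-Aa at 1.35, H2-Ab1 at 1.54 and Mrc1 at -0.83. The call was lost without control replicate 1 (0.0726) and without cKO replicate 3 (0.0580), and the median was 0.41 without control replicate 3. It was 0.37 with normexp at offset 50, 0.43 with the deposited log2 values, 0.43 without the filter on dim probes and 0.46 without the 2 arrays that stood apart. Endothelial markers were higher (median 0.74, 11 genes, camera adjusted p 0.000449; adjusted p = 0.283 with an estimated correlation), with Robo4 at 3.69, Emcn at 1.39, Vwf at 1.27 and Esam at 1.31. The other 2 probes of Robo4 gave 0.23 and 0.31. The list median was 1.14 without cKO replicate 2, 0.40 with normexp at offset 50, 0.42 with the deposited log2 values, and 0.49 without background correction, with cyclic loess and without the 2 arrays that stood apart. Leydig cell markers were not called (adjusted p 0.297, median 0.37), with Star at least 3.11-fold higher, Fabp3 at 1.58, Insl3 at 1.60 and Cyp17a1 at 1.26. Camera called them as higher without control replicate 3 (0.0482, median 0.095) and without the 2 arrays that stood apart (0.0179, median 0.13), and the median was 0.10 without cKO replicate 1 and 0.60 without cKO replicate 3. Red blood cell genes (2 measured) and epididymal and rete genes (4 measured) were too few to test: Alas2 was at -0.35, Hba-a1 at -0.20, Aqp1 at least 1.89-fold higher, Aqp9 at 0.42, Defb15 at 0.24 and Lcn8 at -0.16.

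Over the 24 lists tested, camera called 11, of which 9 were higher and 2 lower. With probes not above background on any control array at their bounds, the medians of the inflammation, extracellular matrix and spermatogonia lists were 1.425, 0.46 and 0.66, and the others did not change. With an estimated correlation camera called 0, and 2 lists had an unadjusted p under 0.05. The directional test fry called 7: S phase, mitosis, p53, extracellular matrix and inflammation, and also D cyclins (0.0406) and immediate early genes (0.0311), which camera did not call. Fry did not call the mature Sertoli (0.167), androgen-responsive (0.243), spermatogonia (0.0641), peritubular (0.0641), leukocyte (0.116) and endothelial (0.0641) lists. With the replicate block fry called 0, with a smallest adjusted p of 0.0737.

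**Figure D2:**
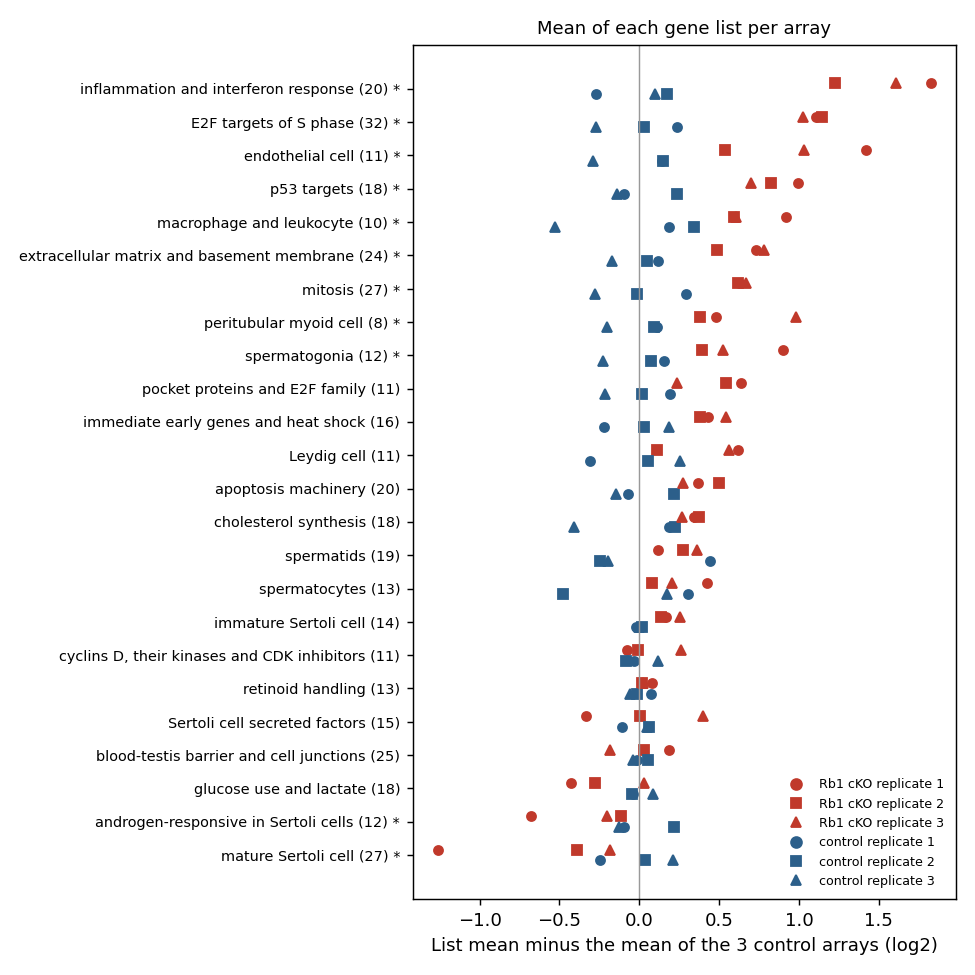
Mean of the measured genes of each list on each array, minus the mean of the control arrays (log2, x axis), with the number of measured genes in brackets and an asterisk where camera's adjusted p was under 0.05. All 3 cKO arrays lie above the 3 controls for S phase and inflammation genes. The same holds for the mitosis, p53, extracellular matrix, spermatogonia, peritubular, leukocyte and endothelial lists. It also holds for lists that camera did not call: pocket proteins, apoptosis, immature Sertoli, cholesterol and immediate early genes. For mature Sertoli cell genes cKO replicate 1 lies lowest, at -1.26.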

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

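The settings that leave out both arrays that stood apart or enter the first within-group component were chosen after the data were seen, and the others before. Every one of the 31 called probes kept a positive difference in each setting that tested it. That was largely fixed in advance, since all 31 had large differences and separated the groups. The number called was less stable. It was 12 probes, all higher, with normexp at offset 50, 13 without background correction, and 1 without a filter on dim probes, where 45281 probes were tested. It was 0 with the replicate block. Leaving out 1 array gave 0 to 16 probes, all higher. Without both arrays that stood apart it was 6, and 5 of these were among the 31. The count was higher with other variance models: 62 with trend and robust (61 higher, 1 lower), and 314 with array weights (298 higher, 16 lower), whose estimation stopped before it converged. The first within-group component as a covariate gave 250 (196 higher, 54 lower), but the component is derived from the same values, and another split of the arrays gave 25 in that setting. With 1 probe per gene, 56 genes were higher and 0 lower, with 12277 tests. Leaving out arrays, dropping the filter and keeping 1 probe per gene change the number of arrays or tests; beyond that the cause was not tested. Cyclic loess, median scaling, the deposited log2 values, detection on all 6 arrays and the fold threshold stayed within 1.5 times. The median difference of all tested probes was 0.08, against -0.04 with cyclic loess and -0.01 with median scaling.

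Camera called 11 lists, 0 with an estimated correlation, and fry called 7. The other settings called 8 to 14, the replicate block 9. Besides the lists named with it in the text, the block changed no call of a list. Camera's direction turned for lists that were not called: the D cyclin list had medians of -0.35 with the deposited log2 values, 0.40 without control replicate 2 and 0.57 without cKO replicate 3 (0.30 to 0.57 over the arrays left out). Secreted factors had 0.11 without control replicate 1 and 0.21 without cKO replicate 3 (0.11 to 0.41). Spermatocytes and spermatids had 0.16 and 0.16 without control replicate 2 (up to 0.64 and 0.56). Retinoid handling had 0.053 without both arrays that stood apart. Medians turned in sign in 9 cases over the alternatives, all of lists that were not called: D cyclins, glucose use, retinoid handling and apoptosis. The medians of called lists moved by over 1.5 times in 31 cases, smaller in size in 30. Among genes, differences near 0 changed sign: Alas2 at 0.018 with array weights and 0.012 without cKO replicate 1 (lowest -0.62), Hba-a1 at 0.16 without control replicate 1 (lowest -0.77), Aqp9 at -0.022 and Defb15 at -0.0038 with array weights, Defb15 at -0.087 without both arrays, and Lcn8 at 0.10 without control replicate 2 (lowest -0.37). Of the remaining values of named genes under other settings, 1895 stayed on their side of the threshold, 157 lost a call and 49 gained one. Most named genes were not called in the main fit, so most of the 1895 had no call to lose. The 157 fall on the few called genes, whose calls were thus often lost. For lists these numbers were 346, 14 and 16. The cause of these changes was not tested. A slide block was not run because no slide is named. Probes near background are limited by signal: 11 of the 31 were undetected on every control array.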

Other observations

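In this part, only the comparisons with other splits of the arrays were chosen before their results were seen; the other tests were chosen after. Further genes past the threshold lay outside the rule for named genes, H2-T23 because its brightest probe did not pass, and are given here as chosen after their values were seen. Gch1, the first enzyme of tetrahydrobiopterin synthesis, rose by 2.91 ± 0.35 (SE), Tagln2 by 2.65 ± 0.25, Dmkn by 2.64 ± 0.33, Cdca7 by 2.23 ± 0.23 and Cyba, a subunit of the phagocyte oxidase, by 2.18 ± 0.26. Rin2 rose by 2.89 ± 0.30 and was detected on 1 control array. Itga5, the fibronectin receptor subunit, and Casp4, an inflammatory caspase, were undetected on controls and at least 4.81-fold and 4.10-fold higher in cKO. H2-T23, a nonclassical MHC class I gene, was called on 1 probe, at least 8.94-fold higher, but its other 2 probes gave 0.50 and 0.23.

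Probes of the same gene were compared where both were detected on all 6 arrays. For probes over 2 log2 units apart between cKO and control, the other probe followed by over 1 unit in 57.1% of 35 pairs. For probes over 2 units apart between cKO replicate 1 and the other cKO arrays, it followed in 25.3% of 348 pairs, and lay within 0.5 of no difference in 50.6%. For control replicate 3 against the other controls the shares were 32.5% and 42.0% of 369 pairs. Low shares were not particular to these arrays: the other probe followed in 23.0% of 270 pairs for cKO replicate 3, 25.9% of 81 for control replicate 2, 32.8% of 64 for control replicate 1 and 0% of 4 for cKO replicate 2. Pairs of one gene are not independent.

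The number of called probes was 31 in the real split of the 6 arrays and at most 1 in the other splits; the number of lists was 11 and at most 10. The real split was the only one of 10 to reach its count in either case (1 split), and 10 splits are too few for a share under 0.05. Among the 3 other splits that also part all 3 numbered pairs, the highest counts were 0 probes and 9 lists.

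S phase genes were higher in cKO. Dividing germ cells carried through the sort were predicted to raise spermatogonia markers at least as much. The S phase mean instead exceeded the spermatogonia mean by 0.49 ± 0.16 (SE) log2 units more in cKO than in controls. The arrays did not overlap (cKO 0.97 to 1.52, controls 0.72 to 0.85). This cannot decide the question, because a log2 rise depends on a gene's control level. Some markers lay near background in controls, such as Ret at 4.71 and Sohlh2 at 5.15. Of the 12 markers, 9 were detected on all control arrays and 0 are in another list. Spermatogonia markers were higher too, so dividing germ cells as a source stay open. The 2 arrays that stood apart do not account for the S phase rise, as the median was 0.84 without them. A response to loss of Rb1, which restrains E2F factors, is the hypothesis that the design offers, and chance stays open. An effect of Cre, which only the cKO samples carried, stays open too. Each number is shared by a cKO and a control array, so an equal effect on both would not raise cKO over control. Within the numbered pairs the S phase list mean differed by 0.87, 1.11 and 1.30. These values cannot test such an equal effect, because it cancels within each pair. An effect that is unequal within a pair was not tested. With the block, the adjusted p was 4.98e-15 in camera and 0.0737 in fry.

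Inflammation and interferon genes were higher in cKO. Leukocytes carried through the sort were predicted to raise leukocyte markers as much. The inflammation mean instead exceeded the leukocyte mean by 0.84 ± 0.34 (SE) more in cKO. The arrays barely parted, with the lowest cKO array and the highest control array both at 0.89 (0.8881 and 0.888). This cannot decide the question, because a log2 rise depends on a gene's control level. Some leukocyte markers lay near background in controls, such as Adgre1 at 5.06 and C1qa at 5.11. Of the 19 list genes on the array, 9 were not tested. Among these, Ptprc, Itgam and Tyrobp, abundant in leukocytes, were not above background on any array. Cd14, Csf1r, Lyz2 and Cd79b were above background on 2 arrays, and C1qc and Cd3e on 1. Of the 10 tested, 8 were detected on all control arrays. Without the 2 arrays that stood apart the inflammation median was 1.30, so these arrays do not account for the rise. Leukocytes as a source stay open, and neither a response of the Sertoli cells nor handling was tested.

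Mature Sertoli cell genes were lower in cKO, but the median shrank from -0.43 to -0.18 without the 2 arrays that stood apart, so those arrays may account for part of it. Leaving them out breaks 2 of the numbered pairs, and within pairs the list mean differed by -1.02, -0.42 and -0.40, where the pair at -0.42 holds neither array and the list was called with the block (camera adjusted p 2.36e-06), but not with an estimated correlation (adjusted p = 0.283, without the block) or by fry with the block (0.0849), so a decrease apart from those arrays stays open. A lower share of Sertoli cells was predicted to raise markers of every other cell type alike. That holds only if the other cells kept their proportions to each other. The endothelial mean differed by 0.76 ± 0.36 (SE) more than the spermatocyte mean, the widest gap among the 7 tested lists of other cells. The arrays overlapped, and these 2 lists were picked by these same values as the largest and smallest rise. A log2 rise also depends on a gene's control level, so this explanation cannot be told apart from a change within the cells. The sort by Sox9-GFP is a gate meant to remove other cells, yet Prm1 showed abundant germ cell RNA in both groups. Sox9 itself, chosen after its values were seen, differed by -0.39 on probe ILMN_2778151 and by -1.215 on probe ILMN_3007428. Neither passed (adjusted p of 0.766 for each in limma), and whether this altered the sort was not tested.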
